A study of Rattus norvegicus with 22 samples.

How the data were processed

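RNA was measured by sequencing in 22 samples of rat microglia in 5 groups. Per the labels' protocols, cells were taken from brains at postnatal day 21 by panning on a CD11b antibody, and libraries were made from poly-A RNA by a full-length protocol with tagmentation and sequenced in pairs. The labels say that libraries were made and sequenced in 2 batches with each condition in both, but do not say which sample was in which batch, so no batch entered the test. The values are FPKM (fragments scaled to transcript length and to the fragments sequenced) as deposited by the authors, 1 column per sample and 17284 gene symbols, with 0 duplicate symbols and 0 columns outside the 22 samples. HISAT2 2.0.3, Cufflinks 2.2.1 and the rat build rn6 are named, per the submitters' processing notes, without role or settings. The gene annotation, any filter and any scaling between libraries are not given in the sources used here. Of the symbols, 14810 matched a current symbol and 2088 only a synonym in a RefSeq table of assembly GRCr8, which served for this count alone. Genome positions and sequences were not used here. The series design calls the samples biological replicates and does not say which came from the same animals or preparation. Genes that share reads with near-identical copies, such as the ribosomal protein, chemokine and MHC families, are uncertain where the authors' estimate could divide reads between them.

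FPKM were taken as log2(FPKM + 1), with a pseudocount of 1, so a fold change is on the log2(FPKM + 1) scale and understates the change of low genes. Genes with at least 1 FPKM in at least 3 samples (9691) were tested, and 5203 genes were at 0 in every sample. All 22 samples entered 1 fit of 5 group means in limma 3.58.1 under R 4.3.3, with moderated variances that followed a trend with mean expression and were robust to outlying genes. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p values in the text are limma's, or those of its camera test for a list. The comparisons were TIC with Acute, FCS 1d, 3d and 5d each with TIC, FCS 5d with FCS 1d, and FCS 5d with Acute. FPKM are given as mean ± SD, and log2 changes with their SE from the fit. An exact 0 may be a failed estimate rather than an absent transcript, so where a group holds zeros the values of its libraries are given instead of a mean.

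The groups, tests, filter, alternatives, rule for named genes and 30 gene lists were set before the data were examined. The rule named, in each comparison, the 8 largest rises and the 8 largest falls among called genes whose libraries did not overlap, 20 fixed genes whatever their result, and in each list up to 4 called members with the largest change and up to 2 going against most of the list. The text names part of the genes the rule allows. Lists covered microglial identity and transcription factors, disease-associated genes, cytokines, interferon response, antigen presentation, alternative activation, cell cycle, cholesterol synthesis, LXR targets, phagocytic receptors, lysosome, immediate early genes, TGF-beta response, glycolysis, actin, growth factors and proteases, amino acid stress, antioxidant response, border macrophages, other blood and brain cells, ribosomal proteins and oxidative phosphorylation. Lists share members, such as the C1q genes, Ctss and Apoe. The 28 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation.

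FPKM hold no read totals, so depth per sample and the counting error of a value are unknown. The steps between low values of the same gene gave an estimate of depth relative to TIC 1. It was 0.85 to 1.1 times in 7 of the 10 libraries with many zeros, and 1.5 to 4.8 times in 10 of the 12 with few zeros. No clear step was found in Acute 1, Acute 2, TIC 5 and TIC 6. A gene listed at 0 in a library with many zeros is therefore weaker evidence than in one with few. The closest libraries, FCS 3d 2 and FCS 3d 4, correlated at r = 0.979 across genes and shared 0 identical tested values above 0.

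The fit was tested on simulated data for each comparison, with 100 genes changed by 2-fold and 100 by 4-fold among 9691 genes. It recovered 73% of 4-fold and 21% of 2-fold changes for TIC with Acute, 81% and 35% for FCS 1d with TIC, 71% and 21% for FCS 3d with TIC, 74% and 27% for FCS 5d with TIC, 73% and 25% for FCS 5d with FCS 1d, and 62% and 11% for FCS 5d with Acute. False calls numbered 6, 5, 1, 4, 8 and 5 in that order. The simulated libraries varied independently, with 1 spread per gene, and held none of the differences between sets of libraries described below. These rates may therefore not hold for the real samples. Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, median-of-ratios rescaling, quantile normalization, a fit of only the groups compared, a replicate block, the first principal component as a covariate, array weights, plain variances, a minimum change of 2-fold, and leaving out each sample in turn. Fits with the summed-FPKM or zero division as a term, and within each division, were chosen after seeing the data. Acute 3 is the lone Acute library with few zeros and FCS 5d 1 the lone FCS 5d library with many; those fits pool the spread over all groups of the division and assume that the lone library varies like the others, and the ranges of p in the text include them. Other splits of the samples were counted over at most 100 draws with seed 1, and unchanged groups were simulated 100 times. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.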

Results

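RNA sequencing measured gene expression in microglia, the resident macrophages of the brain, taken from Sprague-Dawley rats at postnatal day 21 by panning on an antibody to CD11b. The 22 samples form 5 groups: freshly isolated cells (Acute, n = 3), cells kept for 8 days in serum-free TIC medium (TIC, n = 6), and cells kept as long whose medium held 10% fetal calf serum during the final 1 day (FCS 1d, n = 5), 3 days (FCS 3d, n = 4) or 5 days (FCS 5d, n = 4). TIC is the labels' name for the medium, whose composition they do not give. The series design calls the samples biological replicates. The table lists 17284 genes by symbol in FPKM, and 9691 genes with at least 1 FPKM in at least 3 samples were tested. Genes are named by the symbols in the table, and their genome positions were not used here.

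Each library had between 8115 and 9111 genes at 1 FPKM or more. FPKM values carry no read totals, so absolute depth is unknown. Summed FPKM fell into separate ranges, 564301 to 696703 in 6 libraries (the 3 Acute libraries, TIC 5, TIC 6 and FCS 1d 5) and 335470 to 434577 in the other 16. The number of tested genes listed at 0 also fell into separate ranges, 353 to 672 in 12 libraries and 934 to 1295 in 10. Both divisions were drawn after seeing the data. The labels describe 2 batches of library preparation and sequencing, each holding every condition, without saying which sample was in which, so neither division is called a batch here. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.89 to 0.96 between TIC libraries, 0.84 to 0.86 between Acute libraries and 0.66 to 0.77 between Acute and TIC libraries.

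**Figure D1:**
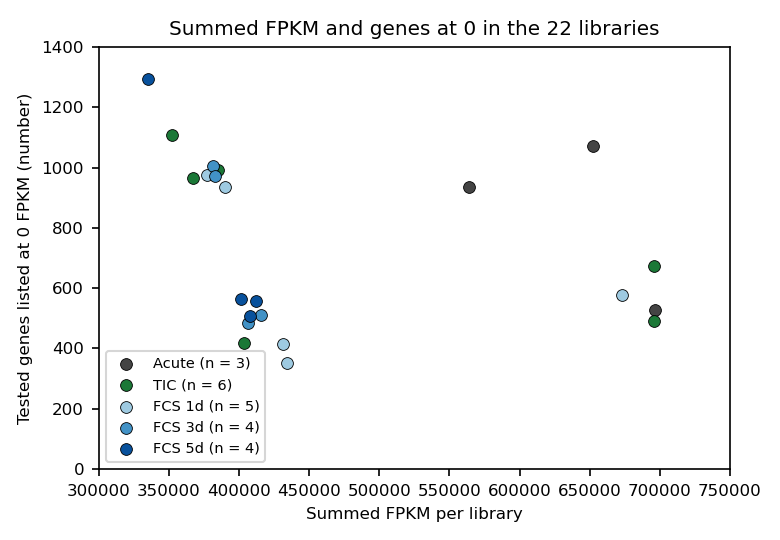
Summed FPKM of each library (horizontal axis) against the number of the 9691 tested genes listed at 0 (vertical axis), 1 point per library, coloured by group (n = 3 to 6). The 6 libraries at 564301 or more are set apart from the 16 at 434577 or less, and all 3 Acute libraries are among the 6.

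The comparison of TIC with Acute asks what 8 days in serum-free TIC medium changed against freshly isolated cells. Genes that mark resident microglia were far lower in TIC. The purinergic receptor P2ry12 fell from 698 ± 332 FPKM (SD, n = 3) to 4.73 ± 2.71 FPKM (SD, n = 6), and the surface protein Tmem119 from 1460 ± 611 to 16.1 ± 6.1 FPKM. The fractalkine receptor Cx3cr1 fell from 2520 ± 625 to 28.0 ± 24.9 FPKM and the transcription factor Sall1 from 92.8 ± 42.4 to 1.61 ± 0.485 FPKM. The complement genes C1qb and C1qc fell by 7.97 and 7.72 on the log2(FPKM + 1) scale. Of 37 tested members of a list of homeostatic microglia genes, 33 were lower and 1 higher, with the same numbers adjusted over the list alone. The list took 10.6 to 25.3% of FPKM in Acute and 0.909 to 1.23% in TIC, and it fell as a set (camera adjusted p = 1e-19, and adjusted p = 0.012 with an estimated correlation).

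The lysosomal gene Ctss fell by 4.84 and the matrix gene Sparc by 7.11 on that scale. The growth factor receptor Csf1r was 2330 ± 691 FPKM in Acute and 486 ± 112 FPKM in TIC (log2 -2.24 ± 0.24 SE, limma adjusted p = 8.5e-08), and Aif1 (IBA1) was at log2 -2.06 ± 0.36. Trem2, a lipid-sensing receptor, was at log2 -2 ± 0.51 (adjusted p = 0.0032), but at -0.81 (adjusted p = 0.1) with the summed-FPKM division as a term; over its alternatives the p ran from 2.6e-07 to 0.42. The lipid carrier Apoe fell from 15100 ± 7100 to 1020 ± 1010 FPKM (adjusted p = 3.1e-05). For Apoe, the TIC libraries with high summed FPKM, TIC 5 and TIC 6, held 2369 and 2270 FPKM and the other 4 held 251 to 643 FPKM.

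Gpnmb, a lysosomal glycoprotein, rose in TIC from 30.7 ± 14.4 to 4330 ± 2120 FPKM, and Spp1 (osteopontin) from 27.7, 0.35 and 4.86 FPKM in the Acute libraries to 9800 ± 7320 FPKM. Spp1 spread widely within TIC, at 17898 and 16214 FPKM in TIC 1 and 3 and 1278 and 883 FPKM in TIC 2 and 4. Lpl, a lipoprotein lipase, was listed at 0, 1.2 and 1.99 FPKM in the Acute libraries and stood at 670 ± 113 FPKM in TIC. The fatty acid carrier Fabp5 was listed at 1.6, 3.93 and 0 FPKM in Acute and stood at 1160 ± 208 FPKM in TIC. Of 34 tested genes of a disease-associated microglia list, 18 were higher and 6 lower (18 and 7 adjusted over the list alone), and the set call (adjusted p = 7.8e-06) was lost at adjusted p = 0.25 with an estimated correlation. The list of LXR targets and lipid handling had 15 of 29 higher and 4 lower (15 and 5 adjusted over the list alone), including the cholesterol exporter Abca1 at log2 3.38 ± 0.28. Its set test gave adjusted p = 1.2e-05 and, with an estimated correlation, adjusted p = 0.062.

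Cytokines and chemokines were higher in TIC. The chemokine Ccl7 rose from 15.2 ± 8.81 to 1600 ± 608 FPKM, and the cytokine Il1b from 46.8 ± 20.5 to 373 ± 112 FPKM. Ccl2 was at 28.4, 727 and 6.18 FPKM in Acute 1, 2 and 3 and at 2910 ± 865 FPKM in TIC. Its rise of log2 5.70 ± 0.88 was 7.58 without Acute 2 and 4.25 without Acute 3. Ccl4 was listed at 0, 26.0 and 8.64 FPKM in Acute and stood at 628 ± 354 FPKM in TIC. Of 36 tested cytokine and chemokine genes, 22 were higher and 1 lower (23 and 1 adjusted over the list alone), a set call that held with an estimated correlation (adjusted p = 4.9e-11 and adjusted p = 0.012). Of 41 interferon response genes, 20 were higher and 1 lower (20 and 1 adjusted over the list alone), led by Usp18 at 5.74 ± 5.66 and 60.9 ± 23.1 FPKM. The set test gave adjusted p = 9.8e-07 and, with an estimated correlation, adjusted p = 0.23. It gave adjusted p = 0.19 among high summed-FPKM libraries (over its alternatives from 7.5e-10 to 0.23), and the list took 0.183 and 0.231% of FPKM in TIC 5 and TIC 6 against 0.468 to 0.662% in the other 4 TIC libraries. Oas2 was listed at 0 in the 3 Acute libraries and between 0.34 and 31.3 FPKM in TIC.

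The actin cytoskeleton and adhesion list had 23 of 41 higher and 4 lower (23 and 5 adjusted over the list alone), among them the adhesion receptor Cd44 (10.6 ± 10.0 and 212 ± 45.8 FPKM) and Anxa5 (24.2 ± 6.25 and 506 ± 134 FPKM). The antioxidant list had 12 of 25 higher and 2 lower, with Nqo1 and Sod2 up by log2 3.61 ± 0.32 and 3.64 ± 0.36. The glycolysis and hypoxia list had 18 of 33 higher and 4 lower, with the lactate transporter Slc16a3 at log2 3.40 ± 0.65. Adjusted over the list alone these last counts were 12 and 2, and 18 and 5. These set calls (adjusted p = 1.1e-10, 9.3e-06 and 7.2e-06) were each lost with an estimated correlation (adjusted p = 0.11, 0.16 and 0.17). Among the falls, Cd74, the class II invariant chain, went from 2260 ± 1240 to 21.8 ± 10.6 FPKM, and RT1-Da was at 355, 406 and 639 FPKM in Acute and at 0 to 3.11 FPKM in TIC. How much Cd74 and RT1-Da in Acute came from blood cells, whose transcripts are described below, was not tested. The whole antigen presentation list was mixed, with 4 of 25 higher and 9 lower (the same adjusted over the list alone, set adjusted p = 0.079, over its alternatives from 0.018 to 0.52). The proliferation marker Mki67 stood at 5.38 ± 3.19 FPKM in Acute and 5.27 ± 2.76 FPKM in TIC (adjusted p = 0.95, over its alternatives from 0.041 to 0.98).

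Transcripts of blood cells and of oligodendrocytes were higher in Acute than in TIC. The neutrophil gene S100a9 was at 1267, 11587 and 6765 FPKM in the 3 Acute libraries, the eosinophil gene Prg2 at 313, 2690 and 1055 FPKM and the haemoglobin gene Hba1 at 995, 456 and 1361 FPKM, and all were listed at 0 in every cultured library. Of the monocyte and neutrophil list, 19 of 23 were lower and 2 higher (adjusted p = 1.9e-12, and adjusted p = 0.098 with an estimated correlation). Of the lymphocyte and NK list, 11 of 14 were lower (adjusted p = 4.5e-08 and, with an estimated correlation, 0.012), among them the B cell gene Cd79b at 67.1, 50.9 and 154 FPKM in Acute and 0 to 1.37 FPKM in TIC. Of the oligodendrocyte list, 7 of 10 were lower (adjusted p = 0.00066, and adjusted p = 0.098 with an estimated correlation), among them Enpp2 at 32.4 ± 11.6 FPKM in Acute and 0 to 0.26 FPKM in TIC. All 4 tested red blood cell genes and both tested fibroblast genes were lower, lists too short for a set test. Adjusted over the list alone, the counts for these lists were the same. The other-cell lists together took 1.24 to 5.16% of FPKM in Acute and 0.237 to 0.314% in TIC. Neuron, astrocyte, and endothelial and mural lists had 2 of 5, 3 of 7 and 3 of 10 lower and 1, 0 and 4 higher, the same adjusted over the list alone, and did not pass as sets (adjusted p = 0.66, 0.21 and 0.28; over their alternatives from 0.42 to 1, 0.024 to 0.64 and 0.19 to 0.99). The endothelial and mural list took 0.0184 to 0.0312% of FPKM in TIC and 0.00559 to 0.0159% in Acute.

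In all, 4106 of 9691 genes differed between TIC and Acute (1424 higher, 2682 lower; limma, Benjamini-Hochberg adjusted p under 0.05, two-sided). The median gene lay at log2 -0.29, and changes are to be read relative to it: with median-of-ratios rescaling the split was 2022 higher and 1981 lower, and with quantile normalization 2012 and 1919. With the summed-FPKM division as a term it was 1963 and 1763. Among high summed-FPKM libraries alone (3 Acute, 2 TIC) 934 genes were called (507 higher, 427 lower). The excess of falls thus depends on scaling and on that division. Among the libraries with few zeros 1974 genes were called (Acute 3 as the lone Acute library) and with many zeros 3887. No Acute library had low summed FPKM. Ccl2, Usp18, Oas2 and Aif1 kept their direction among high summed-FPKM libraries, at log2 5.2, 2.59, 1.41 and -1.41. Their limma adjusted p there was 0.088, 0.065, 0.22 and 0.096 (each the highest over that gene's alternatives, the lowest being 1e-08, 6.7e-07, 7.2e-06 and 1.9e-08).

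**Figure D2:**
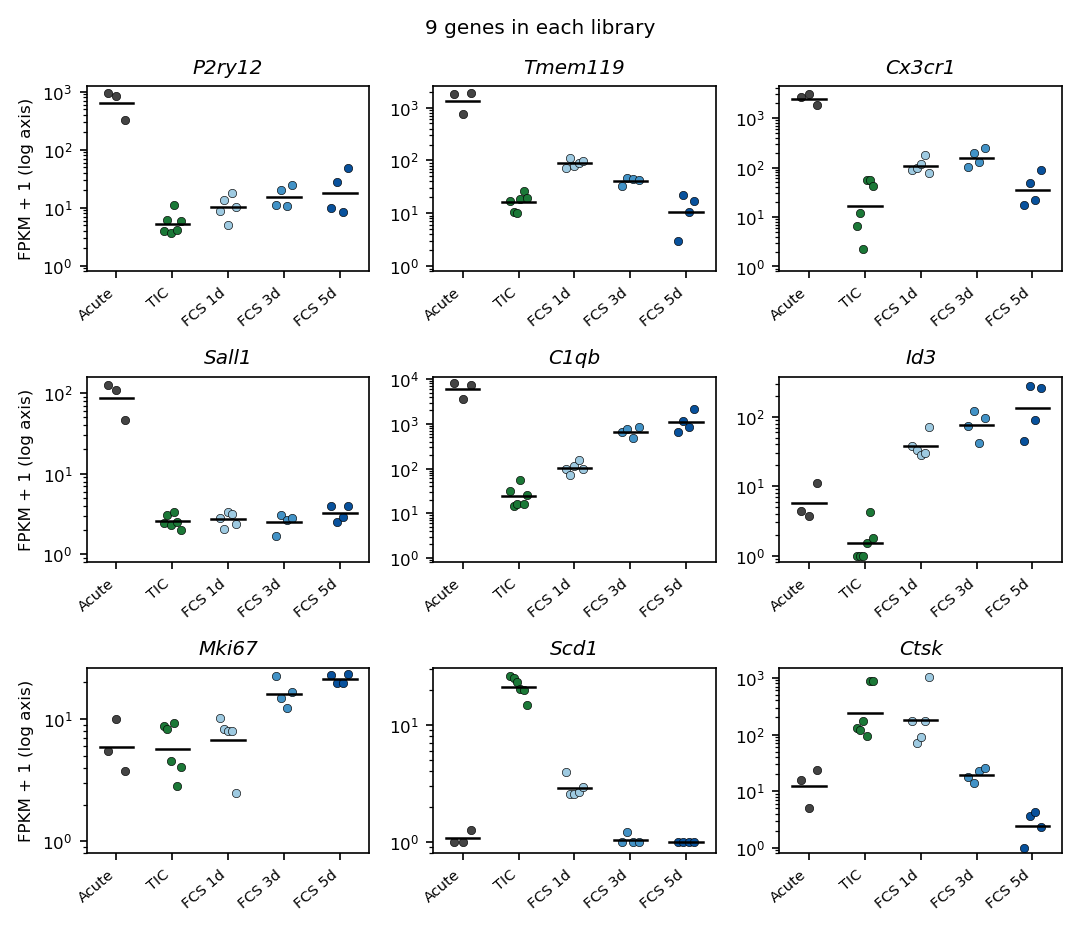
FPKM + 1 of 9 genes in each library on a log axis, 1 point per library, with the 5 groups side by side and a bar at each group's geometric mean. P2ry12, Tmem119, Cx3cr1 and Sall1 are lower in every cultured group than in Acute; C1qb and Id3 are higher in each serum group than in TIC, and Scd1 and Ctsk are lower at FCS 5d than in TIC.

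The comparison of FCS 1d with TIC asks what the last day with serum changed. Several genes of lipid and sterol synthesis fell. The fatty acid desaturases Scd1 and Scd2 fell from 20.6 ± 4.2 (SD, n = 6) to 1.95 ± 0.6 FPKM (SD, n = 5) and from 450 ± 84.7 to 69.4 ± 5.92 FPKM. Their regulator Srebf1 fell from 52.9 ± 8.3 to 8.41 ± 2.04 FPKM. The sterol sensor Insig1 fell from 44.1 ± 13.9 to 8.97 ± 5.9 FPKM. Hmgcs1, also on the cholesterol list, was not called (limma adjusted p = 0.88, with log2 -0.53 to 0 over its alternatives). Of 24 cholesterol synthesis genes 7 were lower and none higher (12 and 0 adjusted over the list alone), and of 29 LXR target and lipid genes 9 were lower and 1 higher (13 and 1 adjusted over the list alone). Both set calls held with an estimated correlation (adjusted p = 7.2e-12 and 2.2e-08, and with an estimated correlation adjusted p = 0.0098 for each).

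Amino acid stress and unfolded protein genes were lower as well, 8 of 26 with none higher (12 and 0 adjusted over the list alone; adjusted p = 9.9e-11, and adjusted p = 0.0098 with an estimated correlation). They included the serine synthesis enzyme Phgdh (21.9 ± 5.99 and 7.08 ± 2.97 FPKM) and Nupr1 (36.3 ± 17.1 FPKM in TIC, 0 to 8.53 FPKM at FCS 1d). The chemokines Ccl4 and Ccl12 fell, with log2 changes of -4.20 ± 0.62 and -3.27 ± 0.58, and so did Tnf, from 70.2 ± 30.6 to 14.2 ± 5.44 FPKM. Il1b stood at 373 ± 112 and 397 ± 154 FPKM (adjusted p = 0.99). Over the 36 cytokine and chemokine genes 5 were lower and 3 higher (7 and 3 adjusted over the list alone; adjusted p = 0.0055, and adjusted p = 0.28 with an estimated correlation), a call also lost among libraries with few zeros (adjusted p = 0.29, over its alternatives from 0.00022 to 0.29). The actin and adhesion list had 5 of 41 lower (10 adjusted over the list alone), with Anxa5 at log2 -1.50 ± 0.27 and S100a6 at -1.73 ± 0.35 (set adjusted p = 3.3e-09, and adjusted p = 0.15 with an estimated correlation).

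The inhibitors of differentiation Id3 and Id1, targets of TGF-beta and BMP signalling, rose. Id3 was listed at 0 in 3 TIC libraries and at 0.51 to 3.31 FPKM in the others, and stood at 38.8 ± 17.5 FPKM at FCS 1d. The TGF-beta list had 4 of 18 higher and none lower (6 and 1 adjusted over the list alone; adjusted p = 5.1e-05, and adjusted p = 0.0098 with an estimated correlation). Against TIC the list did not pass at FCS 3d (4 higher and 1 lower, 5 and 1 adjusted over the list alone; adjusted p = 0.051, over its alternatives from 0.037 to 0.33). Nor did it at FCS 5d (1 higher and 2 lower, the same adjusted over the list alone; adjusted p = 0.78, over its alternatives from 0.55 to 0.99). Part of the homeostatic set rose: Tmem119 from 16.1 ± 6.1 to 89.2 ± 15.5 FPKM, Cx3cr1 from 28.0 ± 24.9 to 112 ± 41.4 FPKM and C1qb from 25.7 ± 15.4 to 105 ± 29.6 FPKM. P2ry12 (4.73 ± 2.71 and 10.0 ± 4.79 FPKM, adjusted p = 0.39, over its alternatives from 0.031 to 0.71) and Sall1 (1.61 ± 0.485 and 1.77 ± 0.562 FPKM, adjusted p = 0.98) did not pass. In the list, 7 of 37 were higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 5.6e-07, and adjusted p = 0.12 with an estimated correlation). The border macrophage list had 2 of 12 higher (5 adjusted over the list alone; adjusted p = 5.1e-05, and adjusted p = 0.0076 with an estimated correlation), one of them the sialic acid receptor Siglec1. The cell cycle list had no member called by limma (7 of 53 at an unadjusted p under 0.05, 7 of them higher), and its set test gave adjusted p = 5.9e-06 and, with an estimated correlation, adjusted p = 0.37.

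In all, 283 genes differed (118 higher, 165 lower; 1201 at an unadjusted p under 0.05). Among the low summed-FPKM libraries alone the count was 615, with more higher than lower (325 and 290). With few zeros it was 129 (42 and 87) and with many zeros 54 (27 of each). The excess of falls was not stable. The call for Id1 (67 ± 20 FPKM at FCS 1d and 18.3 ± 21.3 FPKM in TIC) was lost without TIC 6 or FCS 1d 4 (adjusted p = 0.052 and 0.066). That for Cx3cr1 was lost without FCS 1d 4 (adjusted p = 0.06). Over all alternatives these p values ran from 0.0028 to 0.16 and from 0.0022 to 0.25.

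The comparison of FCS 3d with TIC asks the same of the last 3 days. Cell cycle genes were higher: the kinase Cdk1 stood at 101 ± 15.1 FPKM (SD, n = 4) against 26.6 ± 11.4 FPKM (SD, n = 6) in TIC, thymidine kinase Tk1 at 71.9 ± 1.53 against 13.4 ± 6.28 FPKM and Cdca3 at 47.3 ± 16 against 10.8 ± 6.11 FPKM. Of 53 cell cycle genes, 46 were higher and none lower (50 and 0 adjusted over the list alone; adjusted p = 6.5e-41, and adjusted p = 0.0087 with an estimated correlation). The complement genes C1qa, C1qb and C1qc stood at 222 ± 36.6, 688 ± 157 and 297 ± 67.2 FPKM, against 18.2 ± 7.48, 25.7 ± 15.4 and 20.8 ± 12.5 FPKM in TIC. Id3 reached 81.5 ± 32.7 FPKM and Cx3cr1 168 ± 66.0 FPKM. Tmem119 stood at 40.7 ± 6.45 against 16.1 ± 6.1 FPKM in TIC (log2 1.35 ± 0.40, adjusted p = 0.033). That call was lost in 9 of 26 alternatives. They included leaving out TIC 2 or TIC 3 (adjusted p = 0.068 and 0.073) or FCS 3d 1, 2, 3 or 4 (adjusted p = 0.053, 0.097, 0.082 and 0.081; over all alternatives from 0.0014 to 0.097). Sall1 stayed at 1.56 ± 0.602 FPKM (adjusted p = 0.97). Markers of macrophages at brain borders rose, the mannose receptor Mrc1 from 9.09 ± 3.75 to 52.1 ± 7.98 FPKM and the hyaluronan receptor Lyve1 from 3.68 ± 3.06 to 31.9 ± 10.6 FPKM. Of 12 listed genes 5 were higher (7 higher and 1 lower adjusted over the list alone; adjusted p = 5.1e-06, and adjusted p = 0.0023 with an estimated correlation).

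Lipid synthesis stayed low at FCS 3d. Scd1 was listed at 0 in 3 of the 4 libraries and at 0.21 FPKM in the other, and Scd2 stood at 31.6 ± 3.75 FPKM, log2 -3.78 ± 0.35 against TIC (adjusted p = 2.5e-07). The cholesterol list had 10 of 24 lower and the LXR and lipid list 15 of 29 lower and 1 higher (11, and 16 and 1, adjusted over the list alone), both holding with an estimated correlation (adjusted p = 3.1e-09 and 6.1e-09, and with an estimated correlation adjusted p = 0.02 and 0.0087). Il1rn, the interleukin-1 receptor antagonist, fell from 237 ± 70.0 to 18.3 ± 7.18 FPKM, the chemokine Ccl3 from 1480 ± 291 to 210 ± 35.0 FPKM and Il1b from 373 ± 112 to 151 ± 25.0 FPKM. In the cytokine list 11 of 36 were lower and none higher (13 and 1 adjusted over the list alone; adjusted p = 3e-06, and adjusted p = 0.059 with an estimated correlation). The proteases Mmp9, Mmp12 and Ctsk fell by 3.54, 3.35 and 3.64 on the log2 scale, and S100a6 by 4.29. The stress gene Ddit3 was listed at 0 in all 4 FCS 3d libraries and at 107 to 214 FPKM in TIC. Of 41 interferon response genes 6 were lower (8 adjusted over the list alone), with Ifit3 and Rsad2 at log2 -2.58 ± 0.40 and -2.71 ± 0.44. The set call (adjusted p = 0.035) was lost with an estimated correlation (adjusted p = 0.66) and turned direction among libraries with few zeros (adjusted p = 0.75). Over its alternatives this p ran from 4e-08 to 0.75.

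In all, 977 genes differed (400 higher, 577 lower), 639 higher and 627 lower with quantile normalization. More were higher than lower with the summed-FPKM division as a term (584 and 462), with array weights (1069 and 978) and among low summed-FPKM libraries (1010 and 680). The excess of falls was not stable. The count was 1690 among those libraries, 667 and 187 among those with few and many zeros, and 623 or 619 without FCS 3d 1 or FCS 3d 2. Mki67 (15.5 ± 4.37 FPKM at FCS 3d and 5.27 ± 2.76 FPKM in TIC) lost its call without FCS 3d 1 (adjusted p = 0.065, from 0.00062 to 0.21 over all alternatives).

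The comparison of FCS 5d with TIC covers the longest serum exposure. C1qa, C1qb and C1qc rose from TIC to 590 ± 132, 1220 ± 677 and 788 ± 483 FPKM (SD, n = 4), log2 changes of 5.03 ± 0.35, 5.53 ± 0.37 and 5.16 ± 0.46. Id3 stood at 169 ± 120 FPKM. Mrc1 reached 104 ± 25.9 FPKM, Lyve1 16.1 to 205 FPKM and the ferric reductase Cybrd1 46.0 ± 8.74 FPKM against 1.46 ± 0.916 FPKM in TIC. Rarres1 was at 90.0 to 312 FPKM in the FCS 5d libraries and at 0 to 4.48 FPKM in TIC. The B cell chemokine Cxcl13 was at 3.12 to 88.1 FPKM, against 0 in 5 TIC libraries and 1.31 FPKM in the other. Of the border macrophage list 8 of 12 were higher and none lower (8 and 1 adjusted over the list alone; adjusted p = 4.9e-08, and adjusted p = 3e-04 with an estimated correlation). Cell cycle genes remained above TIC, with Mki67 at 20.4 ± 2.01 and Cdk1 at 98.4 ± 15.3 FPKM and 40 of 53 called higher (46 adjusted over the list alone; adjusted p = 8.5e-32, and adjusted p = 0.023 with an estimated correlation).

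The homeostatic list was mixed at FCS 5d. Tmem119 stood at 12.2 ± 8.28 FPKM against 16.1 ± 6.1 FPKM in TIC (adjusted p = 0.38), Cx3cr1 at 43.5 ± 33.4 FPKM (adjusted p = 0.35, over its alternatives from 0.02 to 0.85) and Sall1 at 2.33 ± 0.747 FPKM (adjusted p = 0.53), while P2ry12 was called higher (adjusted p = 0.012). In the list 11 of 37 were higher and 5 lower (16 and 6 adjusted over the list alone; adjusted p = 4.9e-05, and adjusted p = 0.23 with an estimated correlation). Among the falls were Mmp12 from 296 ± 213 to 2.36 ± 2.13 FPKM, cathepsin K (Ctsk) from 378 ± 388 FPKM to values of 0 to 3.21 FPKM, and the proton pump subunit Atp6v0d2 from values of 11.3 to 177 FPKM to values of 0 to 1.31 FPKM. In TIC and FCS 1d, Ctsk was 877, 880 and 1055 FPKM in TIC 5, TIC 6 and FCS 1d 5, the high summed-FPKM libraries, and 70.2 to 171 FPKM in the others. S100a6 fell from 972 ± 130 to 23.5 ± 18.3 FPKM, Cd44 from 212 ± 45.8 to 36.7 ± 5.31 FPKM and Il1rn from 237 ± 70.0 to 10.1 ± 7.23 FPKM.

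The cytokine list had 15 of 36 lower and none higher at FCS 5d (19 and 0 adjusted over the list alone; adjusted p = 3.7e-08, and adjusted p = 0.023 with an estimated correlation), with Ccl2 at 323 ± 302 against 2910 ± 865 FPKM. Il1b, which was lower than TIC at FCS 3d, was not called at FCS 5d, where its mean FPKM lay above that of TIC. The growth factor Csf1 stood at 1.49 ± 0.379 against 27.4 ± 16 FPKM. Scd1 was listed at 0 in all 4 libraries, and Scd2 stood at 21.6 ± 10.2 FPKM. The LXR and lipid list had 14 of 29 lower and 1 higher (16 and 1 adjusted over the list alone; adjusted p = 2.8e-07, and adjusted p = 0.023 with an estimated correlation), and the cholesterol list 10 of 24 lower (11 adjusted over the list alone; adjusted p = 8.4e-07, and adjusted p = 0.061 with an estimated correlation). Of the disease-associated list 14 of 34 were lower and none higher (18 and 1 adjusted over the list alone; adjusted p = 1e-06, and adjusted p = 0.25 with an estimated correlation), with Fabp5 at log2 -2.36 ± 0.38 and Spp1 at -2.76 ± 1.19 (adjusted p = 0.14, over its alternatives from 0.007 to 0.93). Apoe was at 2000 ± 1240 against 1020 ± 1010 FPKM (adjusted p = 0.18), and passed with the summed-FPKM division as a term (log2 2.21, adjusted p = 0.0012, over its alternatives from 2e-04 to 0.55).

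In all, 1251 genes differed (466 higher, 785 lower), 762 higher and 753 lower with quantile normalization. More were higher than lower also with the summed-FPKM division as a term (678 and 669), with array weights (1233 and 1216) and among low summed-FPKM libraries (1059 and 872). The excess of falls was not stable. The count was 1931 among those libraries, 1481 and 131 among those with few and many zeros (the latter with FCS 5d 1 as the lone FCS 5d library), and 816 without FCS 5d 4; P2ry12 (22.7 ± 19.0 FPKM) lost its call without FCS 5d 2 or FCS 5d 4 (adjusted p = 0.06 and 0.088, from 0.0054 to 0.28 over all alternatives).

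**Figure D3:**
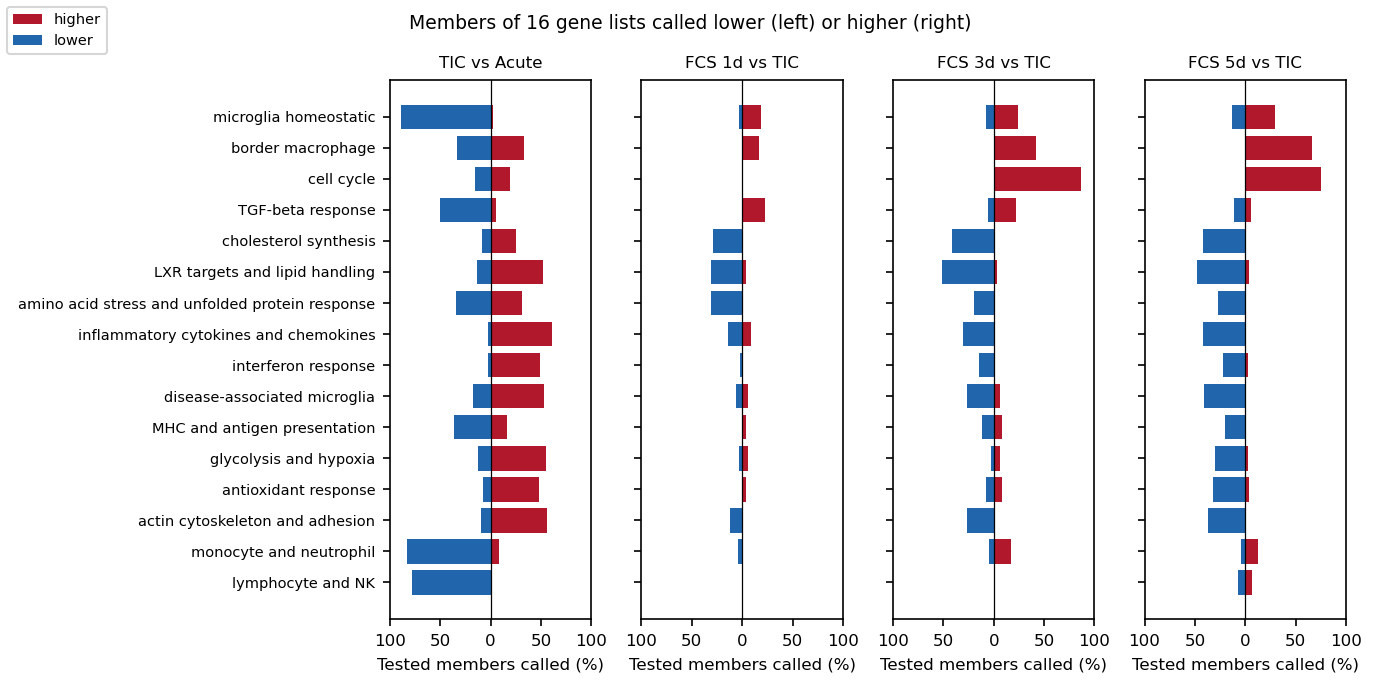
Percent of the tested members of 16 gene lists called higher (right, red) or lower (left, blue) in 4 comparisons, from 0 to 100 on each side. Homeostatic genes are mostly lower in TIC than in Acute (33 of 37), and cell cycle genes are mostly higher at FCS 3d and FCS 5d than in TIC (46 and 40 of 53).

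FCS 5d was also compared with FCS 1d directly, which tests whether the responses to 5 days and 1 day of serum differed. All these cultures lasted 8 days, so serum began earlier in culture at FCS 5d. Its length and its time of onset cannot be told apart. Tmem119 was lower at FCS 5d, at 12.2 ± 8.28 FPKM (SD, n = 4) against 89.2 ± 15.5 FPKM (SD, n = 5; log2 -3.09 ± 0.42, adjusted p = 4.3e-05). C1qa, C1qb and C1qc were higher by log2 2.97 ± 0.37, 3.41 ± 0.38 and 3.45 ± 0.48, and the border macrophage genes Mrc1 and Lyve1 by 2.92 ± 0.28 and 3.05 ± 0.62. For the border macrophage list 4 of 12 were higher (5 adjusted over the list alone, set adjusted p = 0.00075, and adjusted p = 0.037 with an estimated correlation). Its call was lost on ranks and with the replicate block (adjusted p = 0.24 and 0.14, over its alternatives from 0.001 to 0.24). The TGF-beta list was lower at FCS 5d, with 4 of 18 lower and 2 higher (6 and 2 adjusted over the list alone; adjusted p = 0.012). This call was lost with an estimated correlation (adjusted p = 0.11) and among libraries with many zeros, where FCS 5d 1 is alone (adjusted p = 0.057, over its alternatives from 0.0015 to 0.11). Mki67 was 3.18-fold higher on the log2(FPKM + 1) scale, and 19 of 53 cell cycle genes were higher (42 adjusted over the list alone; adjusted p = 1.5e-26, and adjusted p = 0.052 with an estimated correlation).

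The haem oxygenase Hmox1 was lower at FCS 5d, at 366 ± 115 against 2590 ± 635 FPKM and the ferritin chain Fth1 at 6100 ± 1940 against 28600 ± 12200 FPKM. The antioxidant list had 8 of 25 lower and none higher (11 and 0 adjusted over the list alone; adjusted p = 1e-07, and adjusted p = 0.099 with an estimated correlation). The glucose transporter Slc2a1 was at 19.6 ± 7.48 against 76.9 ± 9.33 FPKM and Slc16a3 at 7.84 ± 4.7 against 145 ± 86.3 FPKM, and 11 of 33 glycolysis and hypoxia genes were lower (16 adjusted over the list alone; adjusted p = 2.5e-11, and adjusted p = 0.07 with an estimated correlation). Both lists also leaned higher at FCS 1d than in TIC. At an unadjusted limma p under 0.05, 7 of 25 and 10 of 33 members were higher, and 0 and 1 lower. Those set calls were lost with an estimated correlation (camera adjusted p = 0.28 and 0.26). The antioxidant list took 5.33 to 10.6% of FPKM in TIC, 8.91 to 14.2% at FCS 1d and 3.55 to 5.83% at FCS 5d. The gaps between FCS 5d and FCS 1d thus need not all be a fall from TIC. Fibronectin (Fn1) was at 1.44 ± 0.854 against 10.2 ± 4.3 FPKM, and the fatty acid receptor Gpr84 at 14.5 ± 4.02 against 100 ± 61.9 FPKM. Cx3cr1 (adjusted p = 0.23) and P2ry12 (adjusted p = 0.41) did not pass, but with array weights Cx3cr1 was called lower and P2ry12 higher (adjusted p = 0.028 and 0.033). With the replicate block Cx3cr1 was also called lower (adjusted p = 0.01). Over their alternatives outside the zero division these p values ran from 0.01 to 0.5 and from 0.033 to 0.84. In all 521 genes differed (186 higher, 335 lower); the count was 994 among low summed-FPKM libraries, 647 and 46 among those with few and many zeros (the latter with FCS 5d 1 as the lone FCS 5d library), and 344 without FCS 5d 2.

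Against Acute, FCS 5d cells were low in homeostatic genes. P2ry12, Tmem119, Cx3cr1 and Sall1 were lower, with log2 changes of -5.12 ± 0.55, -7.02 ± 0.48, -6.10 ± 0.80 and -4.72 ± 0.35. In the list, 29 of 37 homeostatic genes were lower with none higher (31 and 0 adjusted over the list alone; adjusted p = 1.9e-15, and adjusted p = 0.015 with an estimated correlation). Cd74 stood at 1.78 ± 1.77 FPKM (SD, n = 4) against 2260 ± 1240 FPKM (SD, n = 3), and 13 of 25 antigen presentation genes were lower and 2 higher, the same adjusted over the list alone (adjusted p = 0.00097, and adjusted p = 0.33 with an estimated correlation). Whether blood cells held part of the Cd74 in Acute was not tested. Blood cell lists were lower in the same comparison, monocyte and neutrophil genes with 19 of 23 lower and 2 higher (adjusted p = 4.2e-12, and adjusted p = 0.13 with an estimated correlation) and lymphocyte and NK genes with 11 of 14 lower (adjusted p = 3.2e-08, and adjusted p = 0.015 with an estimated correlation), the same adjusted over each list alone. Gpnmb (2210 ± 572 against 30.7 ± 14.4 FPKM), Il1b (519 ± 131 against 46.8 ± 20.5 FPKM), Id3 (169 ± 120 against 5.45 ± 4.16 FPKM) and Mrc1 (104 ± 25.9 against 4.06 ± 1.07 FPKM) were higher. The border macrophage list had 7 of 12 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.00037, and adjusted p = 0.015 with an estimated correlation). Ube2c, a mitotic ubiquitin enzyme, was at 146 ± 22.6 against 20.7 ± 18.0 FPKM, and 37 of 53 cell cycle genes were higher and 1 lower (40 and 1 adjusted over the list alone; adjusted p = 1.7e-15, and adjusted p = 0.13 with an estimated correlation). In all 3861 genes differed (1162 higher, 2699 lower). The median gene lay at log2 -0.38, and the split was 1864 and 1862 after median-of-ratios rescaling and 1992 and 1715 after quantile normalization. With the summed-FPKM division as a term it was 1547 and 1220. FCS 5d and Acute share no summed-FPKM range, so no value within a range exists; the counts among libraries with few and many zeros were 2160 and 2651, the first resting on Acute 3 alone in its group and the second on FCS 5d 1 alone.

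The serum responses after 1 and 5 days overlapped. Of the genes called in both comparisons with TIC, 43 were higher in both (5.67 expected of independent lists), 119 were lower in both (13.4 expected) and 8 went opposite ways. Scd2, Insig1 and S100a6 were lower in both, and Id3 and C1qb higher in both. Both comparisons use the same TIC libraries. Simulated unchanged groups gave an overlap of 0, but hardly any gene passes in them, so this cannot measure what the shared libraries add. With TIC split 3 and 3 the overlap of 162 became a median of 75.5 (60 to 109 over 20 assignments), with fewer samples in each comparison. Across the 9691 genes, the change from TIC to FCS 5d had a covariance of -0.45 with the change from Acute to TIC (r = -0.38). TIC enters both with opposite sign, and simulated unchanged groups gave a covariance of -0.06 and r = -0.37, so r alone says nothing here. The covariance differed from the simulated one by -0.39, and with TIC split it was -0.40 (-0.42 to -0.32).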

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

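The tests of explanations and the counts over other splits of the samples were chosen only after the results they bear on were seen, except the count of genes that separate the odd from the even numbers; the differences between FCS 5d and FCS 1d were planned.

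The fall of homeostatic microglia genes from Acute to TIC went with 2 technical differences, since every Acute library had high summed FPKM and held transcripts of blood cells and oligodendrocytes. Among high summed-FPKM libraries alone the 37 tested members had a median log2 change of -3.34 (upper quartile -1.77), which argues against that division as the whole cause. The monocyte and neutrophil list took 7.41 times the share in Acute 2 and 3 that it took in Acute 1 (log2 2.89), while the 37 members had a median log2 ratio of -0.06 (upper quartile 0.85), which argues against these cells as the source; other cell types stay open, untested. The 29 members above 0 in each TIC library had a median of -4.01 (upper quartile -2.24), which argues against failed estimates. That culture itself lowered these genes is a hypothesis, and loss of cell subsets during isolation or culture was not tested.

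Tmem119 was lower at FCS 5d than at FCS 1d, by a test of the difference itself (log2 -3.09). With the division by genes at 0 as a term the change was -3.19, and among low summed-FPKM libraries it was -3.06, so both divisions are argued against. At FCS 3d it stood between them, at 40.7 ± 6.45 FPKM, above TIC at adjusted p = 0.033 (lost in 9 of 26 alternatives, from 0.0014 to 0.097 over all of them); FCS 3d was not tested against FCS 1d or FCS 5d. The age of the culture is the same 8 days in these groups. Serum began earlier in culture at FCS 5d, so its length and its time of onset cannot be told apart. What makes Tmem119 lower there stays open.

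Spp1 was higher in the libraries numbered 1 and 3 than in those numbered 2 and 4 of each cultured group. In all 6 odd and even pairs of the same group and the same zero division the odd library was higher, by at least 6.31-fold and up to 95.5-fold. This argues against that division as the cause in the groups with such pairs. None is at FCS 3d, where 1 and 3 have many zeros and 2 and 4 few. Across the 9691 tested genes, 163 separated 1 and 3 from 2 and 4 the same way in each cultured group, against 47 and 26 for the other pairings of these numbers and 15 by chance. Of the 163, 93 were higher in 1 and 3, among them Spp1, Ccl2, Ccl7 and Nfkb1, and 70 were higher in 2 and 4, among them P2ry12 and Csf1r. These genes also had to separate at FCS 3d, where the numbers and the zero division cannot be told apart. A shared culture preparation of the odd and of the even numbers is a candidate explanation, which the labels do not record.

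Other splits of the same samples were counted for each comparison. The numbers of splits that gave as many genes as the real one include the real one itself, so 1 means that no other split reached it. For TIC with Acute this was 1 of the 84 splits (real 4106, highest other 1589), for FCS 3d with TIC 1 of 100 drawn (977; 347), for FCS 5d with TIC 1 of 100 (1251; 434), for FCS 5d with FCS 1d 1 of 100 (521; 171) and for FCS 5d with Acute 1 of 35 (3861; 1960). No other split tried reached the real count in these comparisons, which argues against chance as the source of these counts. The splits treat the samples as interchangeable, which differences shared by some libraries may break, so chance is not excluded. For FCS 1d with TIC it was 2 of 100 drawn from 462 possible splits, the real split (283) and 1 other. Few splits thus reached the real count, but 1 that mixes the groups passed it, so this count does not exclude chance. That other split, with TIC 5, TIC 6 and FCS 1d 3 to 5 together, called 1197 genes, several times the real count. That points to a structure of the samples. Every library on that side has few zeros, and on the other side only TIC 4 does, so the split nearly follows the zero division. It also puts the 3 high summed-FPKM libraries on the same side. Among low summed-FPKM libraries alone the real split gave 615.

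Single libraries stood apart from the rest of their group in 13 of 236 sets of a named gene and a group (5.51%, where chance gives about 1 in 20). In TIC these were Camp (5.34 FPKM in TIC 5, the rest at 0), Ccl12 (694 in TIC 5, next 1300), Cxcl13 (1.31 in TIC 4, the rest at 0), Fn1 (1.33 in TIC 1), Nkg7 (2.8 in TIC 6, the rest at 0) and Srebf1 (37.3 in TIC 1). At FCS 1d they were Insig1 (19.5 FPKM), Mki67 (1.5) and Glul (402) in FCS 1d 5, the one library of that group with high summed FPKM, and Mertk (15.1) in FCS 1d 1. At FCS 3d it was Scd1 (0.207 FPKM in FCS 3d 2, the rest at 0). At FCS 5d they were Clec4e (0.67 FPKM in FCS 5d 4, the rest at 0) and Itgam (32.2 in FCS 5d 1, next 61.5). Where the rest of a group is at 0, as for Camp, Cxcl13, Nkg7, Scd1 and Clec4e, even a small value can stand out. The chance rate may not hold for such sets. Of 16 sets of library measures 4 stood out. They were the summed FPKM of FCS 1d 5 (672963, next 434577) and of FCS 5d 1 (335470, next 401195), and for FCS 5d 1 also 1295 tested genes at 0 (next 564) and 8115 genes at 1 FPKM or more (next 8388).

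The response to serum differed between 5 days and 1 day in 521 genes, by limma's test of the difference. Higher at FCS 5d were C1qa, C1qb and C1qc (log2 2.97, 3.41 and 3.45), Mrc1 (2.92), Lyve1 (3.05), Cxcl13 (3.93), Cybrd1 (4.37) and Mki67 (1.67). Also higher were Id3 (1.82), Top2a (1.53) and Lpl (1.61), 3 calls that were fragile in other fits too, not only among libraries with many zeros. Id3 lost its call without FCS 1d 1, 2, 3 or 4 (adjusted p = 0.065, 0.071, 0.089 and 0.076) and without FCS 5d 2, 3 or 4 (0.17, 0.05 and 0.16). Top2a lost it without FCS 1d 3 or 5 (0.06 and 0.087) and without FCS 5d 2, 3 or 4 (0.094, 0.074 and 0.094), and Lpl with a pseudocount of 0.1 (0.11). Over all alternatives the adjusted p of these 3 ran from 9.3e-06 to 0.91, from 9.1e-06 to 0.99 and from 1.6e-06 to 0.11, the highest for Id3 and Top2a being among libraries with many zeros, where FCS 5d 1 is the lone FCS 5d library. Lower at FCS 5d were Ctsk (-6.20), Mmp12 (-5.69), Il1rn (-3.43), Slc16a3 (-4.06), Slc2a1 (-2), Hmox1 (-2.85), Fth1 (-2.20), Cd74 (-2.40), Fn1 (-2.17) and Gpr84 (-2.49). Cxcl3 was listed at 0 in all 4 FCS 5d libraries, and its fitted -4.04 is no bound. Among libraries with many zeros, where FCS 5d 1 is alone, all calls named here but C1qa, Ctsk, Mmp12, Hmox1 and Fth1 were lost. Each gene kept its direction there.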

How the results depend on the processing

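Fits with or within the summed-FPKM and zero divisions were chosen only after the data were seen; the other alternatives were set before the data were examined. Over 204 named gene results, 4981 of 5182 alternative values kept direction and side of the threshold, 184 lost the call, 15 gained it and 2 turned direction, and 105 of 187 calls were kept under every setting run. Over 168 gene list results, 1501 of 1652 values were kept, 108 lost, 41 gained and 2 turned. The 4 that turned were among libraries with few zeros: Itgam in TIC and in FCS 5d against Acute (log2 -0.56 and -0.40, adjusted p = 0.27 and 0.42, over their alternatives from 9.8e-08 to 0.34 and from 3.1e-07 to 0.42, each with Acute 3 as the lone Acute library, assumed to vary like the others), and the interferon list at FCS 3d and FCS 5d against TIC (adjusted p = 0.75 and 0.95). Called genes for TIC with Acute (4106) numbered 2727 fitting only the 2 groups, 2353 with the replicate block, 2201 with array weights, 934 among high summed-FPKM libraries and 1974 with few zeros, where Acute 3 is alone in its group (3236 to 4386 without 1 library). For FCS 1d with TIC (283) they were 757 with the replicate block, 515 with the first component, 625 with array weights, 458 with the summed-FPKM term, 615 among low summed-FPKM libraries, and 129 and 54 with few and many zeros (212 to 339 without 1 library). For FCS 3d with TIC (977) they were 1752 with the block, 1543 with the first component, 2047 with weights, 1690 among low summed-FPKM libraries and 187 with many zeros (619 to 954 without 1 library, the lowest being 619 without FCS 3d 2 and 623 without FCS 3d 1). For FCS 5d with TIC (1251) they were 2449 with weights, 1931 among low summed-FPKM libraries and 131 with many zeros, where FCS 5d 1 is alone in its group (816 without FCS 5d 4 to 1262). For FCS 5d with FCS 1d (521) they were 1018 with the block, 996 with the first component, 2156 with weights, 817 with the zero term, 994 among low summed-FPKM libraries and 46 with many zeros, again with FCS 5d 1 alone (344 without FCS 5d 2 to 456). For FCS 5d with Acute (3861) they were 1623 with the block, 2386 with weights and 2160 with few zeros, again with Acute 3 alone (3094 to 4233 without 1 library). Lists past the test fell from 13, 14, 13, 17, 12 and 16 in this order to 3, 5, 4, 4, 1 and 3 with an estimated correlation. With the replicate block the higher and lower calls were 380 and 377 for FCS 1d, 1042 and 710 for FCS 3d and 843 and 700 for FCS 5d with TIC, against 118 and 165, 400 and 577, and 466 and 785 without it. The overlap of 162 serum calls became 75.5 with TIC split and 247 with the summed-FPKM term. The correlation of serum and culture changes (-0.38) became -0.32, -0.50 and -0.33 with TIC split, over called genes and with that term. Fewer samples enter the fits within a division, of 2 groups or with the replicate block. The block fit holds only the 2 groups compared and the numbers that both have. It leaves out TIC 5 and TIC 6 against Acute, FCS 3d and FCS 5d, TIC 6 against FCS 1d, and FCS 1d 5 against FCS 5d, among others. These libraries have high summed FPKM, so there a shift with the block cannot be told apart from leaving them out. The cause of the other shifts was not tested. The labels do not say what a replicate number shares, and in 0 of the 6 comparisons did every same-numbered pair of deviations correlate above 0.1 (-0.11 to 0.52), so the numbers were not taken to pair the samples. As a hint from the data, 15 of 23 pairs correlated best with their own number, and 13 of the 17 between cultured groups. Each of these 17 had 4 or 5 numbers to match, so chance would give fewer, though the comparisons share libraries. The rule of every pair above 0.1 fails on a single low pair, such as FCS 1d number 3 with TIC (r = 0.08). It therefore cannot decide the question, and pairing is not ruled out. The main tests treat all libraries as independent, and their p values would be off if libraries shared a culture. The block ended 6 and gained 7 of the named gene calls, and ended 6 and gained 6 of the list calls, ending among them the border macrophage call of FCS 5d with FCS 1d (adjusted p = 0.14; from 0.001 to 0.24 over all alternatives). The block alone called Apoe higher at FCS 1d than in TIC (adjusted p = 0.0042, against 0.83 without it; from 0.0042 to 0.96), Spp1 lower at FCS 3d and FCS 5d than in TIC (adjusted p = 0.004 and 0.007; over all alternatives from 0.004 to 0.97 and from 0.007 to 0.93), Cx3cr1 higher at FCS 5d than in TIC (0.02; from 0.02 to 0.85) and P2ry12 higher at FCS 1d than in TIC (0.031; from 0.031 to 0.71). Summing duplicate symbols gave no value, as there were 0. FPKM keep no counts, so small differences of low genes were not detectable, and 2-fold changes were recovered in 11 to 35% of simulated genes.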

Other observations

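The lists, their tests and the rule for named genes were set before the data were examined; which of those genes and libraries are mentioned here, and the tests with or within the summed-FPKM and zero divisions, were chosen only after the values were seen. Phagocytic receptors moved in both directions in culture, with 9 of 30 higher and 10 lower in TIC than in Acute (9 and 11 adjusted over the list alone; set adjusted p = 0.5, with a median log2 change of 0.20 and a mean of -0.04). The scavenger receptor Msr1 was listed at 4.64, 0 and 12.4 FPKM in Acute and stood at 338 ± 64.3 FPKM in TIC (SD, n = 6), and the bridging protein Mfge8, which tags dying cells, fell by 4.22 on the log2(FPKM + 1) scale, from 120 ± 42.6 FPKM (SD, n = 3) to 7.74 ± 8.21 FPKM. At FCS 1d the receptor Mertk, which takes up dying cells, stood at 18.2 ± 1.73 against 6.17 ± 3.23 FPKM in TIC (limma adjusted p = 0.0028). At FCS 5d complement C3 and the scavenger receptor Colec12 rose against TIC, to 75.2 ± 22.2 and 56.1 ± 6.6 FPKM, while the integrin Itgb2 fell from 325 ± 78.8 to 106 ± 28.6 FPKM. The list had 7 of 30 higher and 3 lower there (8 and 5 adjusted over the list alone; adjusted p = 0.31, toward higher, with a median of -0.26 and a mean of 0.17). Lysosomal genes were mixed in TIC against Acute (16 of 49 higher, 14 lower, 16 and 16 adjusted over the list alone; adjusted p = 0.27, toward higher, with a median of -0.10 and a mean of 0.12; over its alternatives from 0.0083, with the summed-FPKM division as a term, to 0.84). Against TIC, 11 were lower and 2 higher at FCS 5d (17 and 3 adjusted over the list alone; adjusted p = 0.00092, and adjusted p = 0.59 with an estimated correlation). The 2 lysosomal genes higher at FCS 1d were Ctsc and Psap, at 555 ± 190 against 118 ± 4.96 FPKM and 2780 ± 704 against 1060 ± 323 FPKM in TIC (2 of 49 higher and 0 lower, the same adjusted over the list alone; camera adjusted p = 0.42, over its alternatives from 0.024 to 0.92; with limma at an unadjusted p under 0.05, 6 higher and 4 lower).

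Immediate early genes, which respond to tissue handling, were not uniformly high in fresh cells. Fos was at 940 FPKM in Acute 2 and 21.9 and 13.7 FPKM in Acute 1 and 3, and without Acute 2 its fall to TIC lost the call (adjusted p = 0.17, over its alternatives from 0.00093 to 0.95, the last among libraries with few zeros, where Acute 3 is the lone Acute library). The list took 2.38% of FPKM in Acute 2 and 0.161 and 0.216% in Acute 1 and 3. The stress factor Atf3 was at 2.79, 24.7 and 1.27 FPKM in the Acute libraries and 91.9 ± 62.3 FPKM in TIC, and the list had 7 of 33 higher and 10 lower (7 and 11 adjusted over the list alone; adjusted p = 0.87, toward higher, with a median of -0.92 and a mean of -0.37). At FCS 5d 11 were lower than in TIC and 0 higher (with limma at an unadjusted p under 0.05, 1 higher and 15 lower; 11 and 1 adjusted over the list alone; adjusted p = 5.6e-06, and adjusted p = 0.38 with an estimated correlation), with Ppp1r15a at 12.6 ± 3.69 against 74.6 ± 28.4 FPKM. Of 26 microglial transcription factors 9 were lower and 1 higher in TIC than in Acute (adjusted p = 0.19, over its alternatives from 0.035 to 0.52), and of 16 alternative activation genes 5 were higher and 5 lower (adjusted p = 0.39). The TGF-beta list had 9 of 18 lower and 1 higher (adjusted p = 0.19). Adjusted over the list alone these counts were the same. Growth factor, matrix and protease genes had 11 of 24 higher and 4 lower in TIC (the same adjusted over the list alone; adjusted p = 0.0023, and adjusted p = 0.25 with an estimated correlation) and 9 lower at FCS 5d than in TIC (11 lower and 1 higher adjusted over the list alone; adjusted p = 2.8e-05, and adjusted p = 0.14 with an estimated correlation). Ribosomal protein genes had 28 of 77 higher and 2 lower in TIC (the same adjusted over the list alone; adjusted p = 4.5e-08, and adjusted p = 0.51 with an estimated correlation), and the list took 2.07 to 4.03% of FPKM in Acute, 4.78 to 7.82% in TIC, 4.36 to 6.91% at FCS 1d, 6.53 to 8.59% at FCS 3d and 8.37 to 10.9% at FCS 5d. Against TIC, limma called 0 of 77 at FCS 1d (1 at an unadjusted p under 0.05; the same 0 adjusted over the list alone), with a set test toward lower (adjusted p = 0.016, and adjusted p = 0.89 with an estimated correlation). At FCS 5d 4 were higher (1 adjusted over the list alone; adjusted p = 8.4e-07, and adjusted p = 0.58 with an estimated correlation). Oxidative phosphorylation genes had 9 of 83 higher and 9 lower in TIC (8 and 9 adjusted over the list alone; adjusted p = 0.27, toward higher, with a median of -0.03 and a mean of -0.08). The same direction was called with the summed-FPKM division as a term (adjusted p = 7.8e-06) and among high summed-FPKM libraries (adjusted p = 6.9e-06), and over all alternatives the p ran from 6.9e-06 to 0.84. Amino acid stress genes had 8 of 26 higher and 9 lower, cholesterol synthesis genes 6 of 24 higher and 2 lower, border macrophage genes 4 of 12 higher and 4 lower, and cell cycle genes 10 of 53 higher and 8 lower in TIC than in Acute. Adjusted over the list alone the cholesterol counts were 2 and 2 and the others the same, and the set tests gave adjusted p = 0.43, 0.19, 0.36 and 0.21 (over their alternatives from 0.26 to 0.89, 0.052 to 0.54, 0.18 to 0.93 and 0.047 to 0.77). The amino acid stress list, tested toward higher, had a median of -0.01, and the border macrophage list, also toward higher, a mean of -0.20. At FCS 1d the glutamine synthetase Glul, on the astrocyte list and known in macrophages too, stood at 832 ± 258 against 241 ± 32.2 FPKM in TIC. The astrocyte list had 1 of 7 higher and 0 lower there (3 and 0 adjusted over the list alone, set adjusted p = 0.013). This set call was lost with an estimated correlation, on ranks, with the replicate block and among libraries with few zeros (adjusted p = 0.18, 0.31, 0.052 and 0.12, over its alternatives from 0.0096 to 0.31). It took 0.0384 to 0.0746% of FPKM in TIC, 0.197 to 0.272% in FCS 1d 1 to 4 and 0.0707% in FCS 1d 5, and Glul made up most of that share in each of these libraries. Whether other astrocyte transcripts came with it was not tested further.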
